A study of Escherichia coli with 2 samples.

How the data were processed

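Ribosome footprints of Escherichia coli MG1655, a laboratory K-12 strain, were sequenced in 2 libraries, both from samples frozen in liquid nitrogen. In 1 library the footprints came from single ribosomes (monosomes). In the other they came from collided pairs of ribosomes (disomes). The labels list tigecycline and capreomycin, antibiotics that act on the ribosome, as the treatment of both libraries. There was 1 library of each kind, so there was no replicate and no test between conditions was possible.

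Per the labels' protocols, ribosomes were footprinted with micrococcal nuclease and pelleted, and their RNA was extracted. A preadenylated linker was ligated, rRNA was depleted, and the cDNA was circularized and amplified by PCR. Micrococcal nuclease cuts some bases more readily than others, and rRNA depletion and PCR act before counting, so all of them can shift gene totals. The submitters' processing notes name CASAVA 1.8 and Bowtie2 2.1.0 without giving their roles. The genome build, the read lengths kept, the treatment of reads that match several places, and the rule that assigned a footprint to a gene are not given in the sources used here.

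Each deposited file lists 4294 genes by locus tag, with a gene length in codons and a whole-number count, which was read as raw footprint counts per gene. The deposited counts summed to 21267482 in the monosome library and 8408429 in the disome library. The same locus tags and lengths stood in both files. Locus tags were matched to gene symbols in a RefSeq gene table of assembly ASM584v2. Of the 4294 rows, 4283 matched and 11 did not. For 4076 rows the gene length in that table was exactly 3 times the length in the file, so the lengths of these rows are coding lengths. The other rows do not have this relation or have no match. No coordinates are given because the build behind the counts is not known, and sequences were not used here.

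For each gene the log2 ratio of disome to monosome CPM (counts scaled to the total of all gene rows) was computed, with a prior count of 0.5 only where one count was 0. A negative ratio means a smaller share of the disome library than of the monosome library. Exact Clopper-Pearson 95% intervals, conditional on the sum of both counts, were attached to each ratio. PCR reads without molecular identifiers are not independent molecules, so intervals and limits cover counting error only and say nothing of the spread between cultures. Where the disome count was 0, the difference is given as a lower bound against 3 reads. Genes with at least 100 reads over both libraries were compared. A gene was called higher or lower when its ratio was at least 2-fold, which is a rule of size and not a test.

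Before the data were examined, 32 gene lists were fixed. The median ratio of each list with at least 5 measured protein-coding members was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. A list was said to stand apart below percentile 2.5 or above 97.5. This percentile describes these 2 libraries and is not a p-value. Of the 32 lists, 29 could be placed. The tryptophanase operon had 3 measured members, none of the small toxins of type I systems reached 100 reads, and no name of the list of structural and regulatory RNAs matched a row.

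The genes named were set by a rule fixed together with the lists. Among protein-coding genes with at least 100 reads it took the 10 highest and the 10 lowest ratios, and the highest and lowest member of each list. It also took the 5 genes with the largest share of each library and every listed arrest or leader peptide, whatever its count. Further list members are given as examples of their list and were chosen after their values were seen.

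The computations were tested on simulated data for this comparison, with Poisson counts for 1729 genes and 200 changed genes. All simulated 4-fold changes were called (100.0% of 50 higher and 100.0% of 50 lower). Of the changes of 1.5 on the log2 scale, 100.0% of 50 higher and 98.0% of 50 lower genes were called. Among 1529 unchanged genes, 2 passed 2-fold, and the intervals covered the true value for 95.5% of genes. Poisson counts hold no duplicate reads and no spread between cultures. These rates therefore check the computation and are not the error rates of the calls on the real libraries. Of 200 random lists of 15 genes drawn from the real ratios, 6.5% stood apart. When the same lists were lowered by 1 on the log2 scale, 51.0% were found, so a list can be shifted by that much and still not stand apart.

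Alternatives planned together with the lists were other scalings (trimmed mean of M values from edgeR 4.0.16 and size factors from DESeq2 1.42.0, both in R 4.3.3, and totals without the 10 most counted genes of either library) and other read minimums. Further ones were another prior count, the interval bound in place of the ratio, other matching of random lists, and leaving out pseudogenes or overlapping and near-identical genes. The other computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. A planned comparison of genes with runs of proline was not made because it needs protein sequences, which were not used here.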

Results

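Ribosome footprints were counted per gene in 1 monosome library and 1 disome library of E. coli MG1655, to survey where ribosomes pause and collide. The monosome library held 21267482 reads over 4294 genes and the disome library 8408429. In the monosome library 765 genes had no read, against 1439 in the disome library. Reads were concentrated in few genes. The 10 most counted genes took 26.4% of the monosome reads and 31.0% of the disome reads, and the 100 most counted took 74.8% and 80.7%. With 1 library of each kind no ratio below has a replicate check, and the intervals given are 95% counting intervals.

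The same abundant genes led both libraries. ompC (b2215), a major outer membrane porin, took 4.28% of the monosome and 5.68% of the disome reads. ompA (b0957), an outer membrane structural protein, took 3.66% and 5.27%. lpp (b1677), the murein lipoprotein, took 3.14% and 4.20%. The genes of elongation factor Tu were also among the 5 most counted of each library, with tufA (b3339) at 3.41% and 4.11% and tufB (b3980) at 2.82% and 3.37%. These tuf genes are near-identical copies, so the division of reads between them is uncertain. The count of tufB was 0.827 times that of tufA in the monosome library and 0.820 times in the disome library. Across the 1729 genes with at least 100 reads, monosome and disome counts were correlated with a Spearman rho of 0.845. On the log2 scale of CPM (counts scaled to the library total) Pearson's r was 0.894 over the 1719 genes with reads in both libraries. These are correlations across genes, which are not independent replicates.

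**Figure D1:**
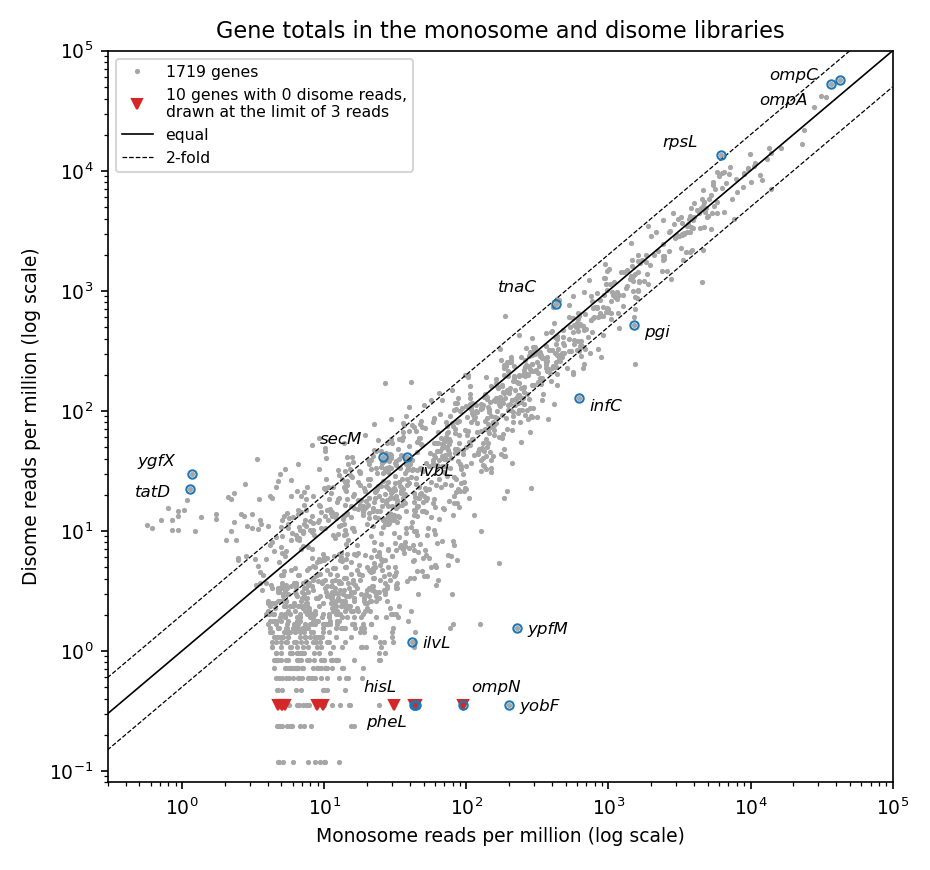
CPM in the monosome library (x axis, log scale) against the disome library (y axis, log scale) for genes with at least 100 reads. Grey points are 1719 genes with reads in both libraries, red triangles are 10 genes with 0 disome reads drawn at the limit of 3 reads, blue circles mark labelled genes, the solid line is equality and dashed lines are 2-fold. ompC and ompA lie just above equality with library totals, and 800 genes lie under the lower 2-fold line.

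The first comparison asked which genes held more or less of the disome library than of the monosome library. Of the 1729 genes, 102 were at least 2-fold higher in the disome library, 800 were at least 2-fold lower and 827 lay within 2-fold. The median gene had a log2 ratio of -0.85 (quartiles -2.16 and -0.07). This centre depends on the scaling. The median moved up by 0.08 with totals without the 10 most counted genes of either library, where 114 genes were higher and 770 lower. It moved up by 0.66 with trimmed-mean factors and by 0.83 with size factors, and the calls were then 267 higher and 577 lower, and 329 higher and 536 lower. The higher share of calls was 11.3% with library totals, 31.6% with trimmed-mean factors and 38.0% with size factors. Ratios and counts of 2-fold members below are relative to library totals, can be read against the median of -0.85, and move with the scaling. Of 24 named genes within 2-fold, 15 were at least 2-fold higher with trimmed-mean factors and 19 with size factors.

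The 10 highest ratios belonged to genes with few monosome reads. ygfX (b2896) had 25 monosome and 249 disome reads, a 25.2-fold higher share in the disome library (interval 16.7 to 39.7). tatD (b4483), a DNase gene, had 24 and 189 reads and a log2 ratio of 4.32 (3.70 to 4.99). recF (b3700), a recombination mediator gene, was 19.8-fold higher (10.8 to 39.7). holA (b0640), the delta subunit of DNA polymerase III, was 17.5-fold higher (10.2 to 32.5). fhuD (b0152), which binds ferric hydroxamates in the periplasm, was 19.5-fold higher with 17 and 131 reads. The flagellar rod gene flgF (b1077) was 17.1-fold higher with 13 and 88 reads. The rRNA methyltransferase gene rsmI (b3146) was 16.6-fold higher, and the potassium efflux gene kefC (b0047) 15.7-fold. The tryptophan repressor gene trpR (b4393) was 14.6-fold higher and the thiamine pathway kinase gene thiM (b2104) 14.4-fold. For these 10 genes the monosome counts lay between 12 and 25. With so few monosome reads, they passed the read minimum over both libraries only through their disome reads. A gene with as few monosome reads and a low ratio would not have been measured. High ratios among measured genes of this kind are therefore set by the rule, and the intervals do not cover this selection.

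At the other end, ompN (b1377), a porin gene related to ompC, had 2016 monosome reads and 0 disome reads, at least 266-fold lower in the disome library. The leader peptide genes pheL (b2598) and hisL (b2018) also had no disome read and were at least 124-fold and 120-fold lower. yobF (b1824), of 48 codons, had 4240 monosome reads and 3 disome reads, a ratio of 559-fold lower with a counting interval of 191 to 2711. ypfM (b4606), of 20 codons, had 4820 and 13 reads and was 147-fold lower (85.6 to 276). pgpA (b0418), a phosphatidylglycerophosphatase gene, had 209 and 0 reads, at least 27.5-fold lower. pptA (b1461) and yjbJ (b4045) had 189 and 113 monosome reads and no disome read, at least 24.9-fold and 14.9-fold lower. rimJ (b1066), which encodes an acetyltransferase of a ribosomal protein, had 271 and 1 reads, 107-fold lower (19.1 to 4247). napD (b2207), a chaperone of periplasmic nitrate reductase, had 217 and 1 reads, 85.8-fold lower (15.2 to 3404). ompN and ompC are related genes, and how reads that match both were counted is not given in the sources used here.

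The second comparison asked how genes that encode peptides known for ribosome arrest, or leader peptides of attenuated operons, were placed. tnaC (b3707), the 25-codon leader whose peptide arrests the ribosome in response to tryptophan, had 9114 monosome and 6518 disome reads. Its log2 ratio was 0.86 (interval 0.81 to 0.90), the highest of this list. secM (b0097), whose peptide arrests translation upstream of secA, had 549 and 347 reads and a log2 ratio of 0.68 (0.48 to 0.87). The leader ivbL (b3672) stood at 0.09 (-0.09 to 0.28). The remaining measured leaders lay far lower. ilvL (b3766) had 887 and 10 reads and a log2 ratio of -5.13 (-6.20 to -4.25), and leuL (b0075) had 98 and 5 reads and a ratio of -2.95. pheM (b1715) had 107 and 0 reads, at least 14.1-fold lower. Below 100 reads, trpL (b1265) had 5 monosome and 0 disome reads, thrL (b0001) had 7 and 0, topAI (b4566), a toxin gene placed on this list, had 0 and 1, and pyrL (b4246) had 0 and 0, too few for a ratio. Over its 8 measured members the list had a median log2 ratio of -4.04, or -3.39 with genes without disome reads at their bound. Matched random lists had a median of -1.03, and the list stood apart at percentile 0.01, with 5 members at least 2-fold lower and 0 at least 2-fold higher. With trimmed-mean factors and with size factors the same tally was 5 and 2, since tnaC and secM then passed 2-fold. The measured members had a median length of 27 codons, and these random lists were matched on expression but not on length. Genes of 21 to 50 codons, leaders among them, had a median log2 ratio of -2.68. The low place of the list therefore cannot be told apart from short reading frames. Downstream of tnaC, the tryptophanase gene tnaA had a log2 ratio of -0.41 and the transporter gene tnaB (b3709) of -1.51, less than 2-fold lower with size factors.

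**Figure D2:**
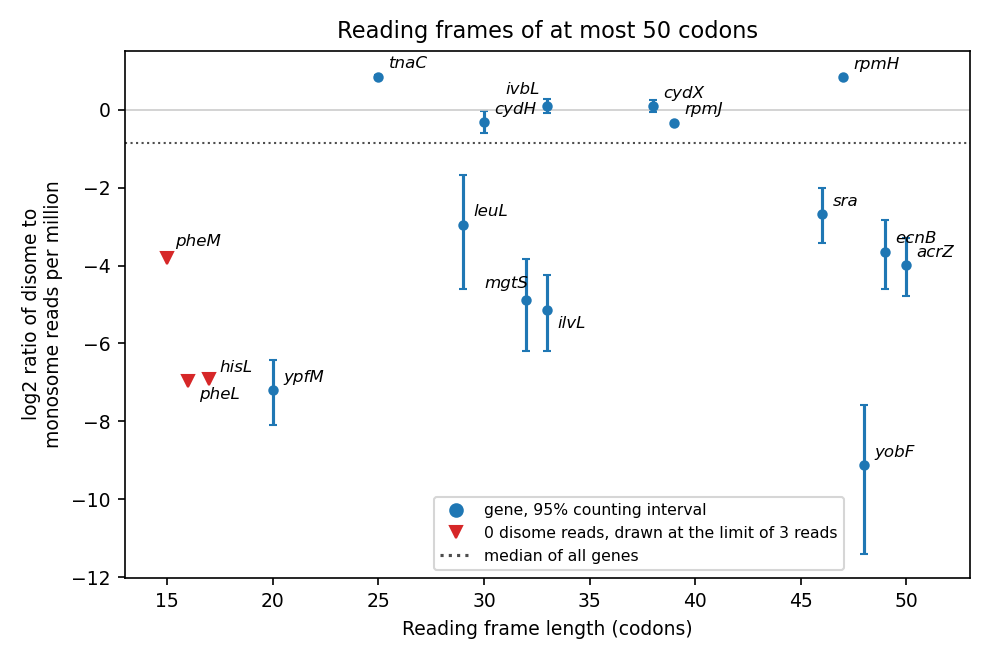
The log2 ratio of disome to monosome CPM (y axis) against reading frame length in codons (x axis) for the 17 genes of at most 50 codons with at least 100 reads. Points carry 95% counting intervals, red triangles are genes with 0 disome reads drawn at the limit of 3 reads, and the dotted line is the median of all genes, -0.85. The 4 genes of at most 20 codons lie far below that median, and tnaC, of 25 codons, lies above 0.

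The third comparison asked whether gene groups were shifted together. Of the 29 lists that could be placed among random lists, 4 stood apart, all on the lower side, where 1.45 would be found by chance if lists were independent. Besides the leader peptides these were outer membrane proteins, nucleoid-associated proteins, and acid and general stress genes.

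The outer membrane proteins had a median log2 ratio of -0.79 against -0.24 for matched random lists (percentile 0.185), and their median was 0.04 with size factors, so the shift is relative to genes of like expression. The median counts each member equally. By reads the list held more of the disome library (17.1%) than of the monosome library (13.7%). Of 17 members, 4 were at least 2-fold lower, 0 at least 2-fold higher and 13 within 2-fold, against 2 lower and 3 higher (ompA, ompC and lpp) with size factors. ompA, at 0.53, was the highest member, and lpp and ompC stood at 0.42 and 0.41. Lower members included ompF at -0.97, a porin gene, and the assembly genes lptD at -2.47 and tamA (b4220) at -2.65. Among 8 genes of nucleoid-associated proteins, 5 were at least 2-fold lower, or 2 with size factors, and the median was -1.25 against -0.42 for matched lists (percentile 0.37). The lowest were dps (b0812), a DNA-binding protein of starved cells, at -3.29 (-3.53 to -3.06), and hns, a global silencer, at -1.96. hupB (b0440) and hupA, which encode the HU subunits, stood at -0.31 and -0.43. The nucleoid-associated list had a median length of 99.5 codons, and these random lists were not matched on length. All 119 measured genes of 51 to 100 codons had a median of -1.27, and 67 were at least 2-fold lower. The list also stood apart with matching on expression and length, but in 3 wide bins of length. Short genes were therefore not set aside as the reason for its low place. The 9 measured acid and general stress genes had a median of -2.18 against -0.84 (percentile 1.82), with 5 at least 2-fold lower and 1 at least 2-fold higher, or 5 and 2 with size factors. Lower members were dps, osmE at -2.89, wrbA at -2.54, osmY at -2.26 and katE at -2.18. The peroxidase gene osmC (b1482) was the highest at 1.17 (0.92 to 1.41). This last list left the outer 2.5% with a prior count of 5 (percentile 3.445) or a minimum of 50 monosome reads (2.815).

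Both lists of ribosomal protein genes had medians above that of all genes and did not stand apart from matched lists. The 21 small-subunit ribosomal protein genes had a median log2 ratio of 0.11 (percentile 61.3) and the 33 large-subunit genes also 0.11 (percentile 83.2). rpsL (b3342), which encodes S12, had 131291 and 113724 reads and a log2 ratio of 1.13 (1.12 to 1.14), the 1 small-subunit member at least 2-fold higher with library totals. With size factors 8 small-subunit and 14 large-subunit genes were at least 2-fold higher. rpsS (b3316) was the lowest of the small subunit at -0.70. In the large subunit rpmH (b3703) reached 0.83, while rpmG (b3636), which encodes L33, stood at -2.65 and rpmI at -1.15. Among 15 translation factor genes the median was -0.38 (percentile 24.7). The initiation factor genes infC (b1718) and infA were at -2.29 and -2.10, against -0.02 for infB. Elongation factor Tu stood at 0.27 and 0.26, elongation factor G (fusA) at -0.47 and EF-P (efp) at -0.38. The 23 aminoacyl-tRNA synthetase genes had a median of -0.48 (percentile 33.1), from hisS (b2514) at 0.91 to lysU (b4129) at -1.85. Of 9 ribosome rescue and hibernation genes, 5 were at least 2-fold lower, or 3 with size factors (median -1.30, percentile 23.1). The lowest was rmf (b0953), the ribosome modulation factor, at -4.09 (-5.23 to -3.15), and the highest was hflX (b4173) at -0.11. smrB, which encodes a nuclease that acts on collided ribosomes, was at -1.30.

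**Figure D3:**
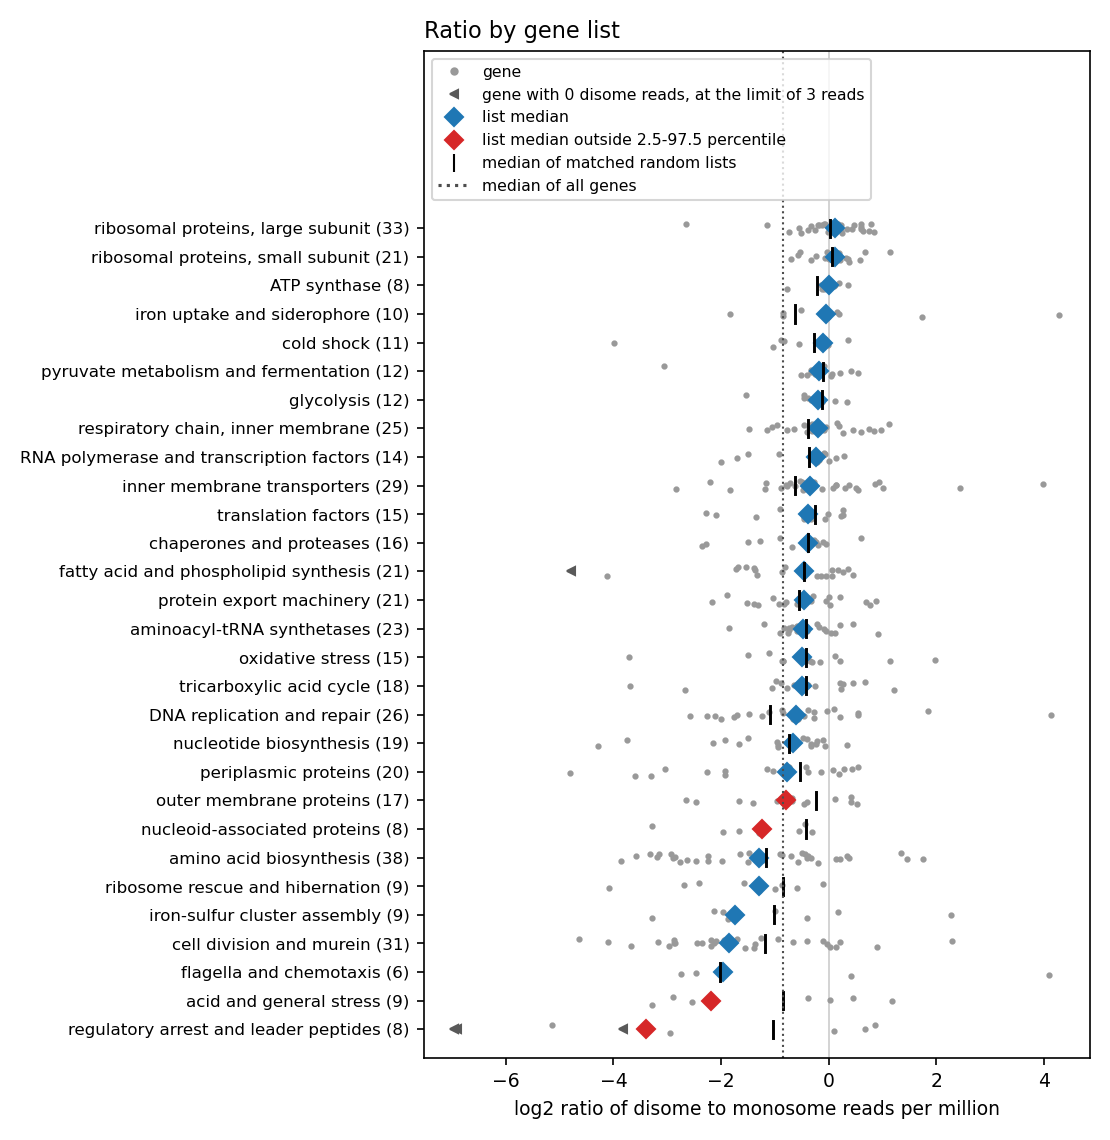
The log2 ratio of disome to monosome CPM (x axis) for the measured members of 29 gene lists (y axis, number of genes in brackets). Grey points are genes, dark triangles are genes with 0 disome reads at the limit of 3 reads, diamonds are list medians with such genes at that limit (red where the list stood apart), black ticks are medians of matched random lists and the dotted line is the median of all genes. The 4 lists in red lie to the left of their matched random lists.

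The medians of the energy metabolism lists also lay above that of all genes, and none stood apart. All 8 measured ATP synthase genes were within 2-fold with library totals, while atpC and atpD were higher than that with size factors (median 0.00, percentile 87.0), from atpB (b3738) at -0.77 to atpC (b3731) at 0.36. The 25 respiratory chain genes had a median of -0.20 (percentile 91.6), with nuoK (b2279) at 1.13 and nuoI (b2281) at -1.49, less than 2-fold lower with size factors. Of 12 glycolysis genes 11 were within 2-fold with library totals (median -0.20, percentile 34.8). The exception was pgi (b4025), phosphoglucose isomerase, with 32216 and 4368 reads 2.92-fold lower (2.83 to 3.01), though not 2-fold lower with size factors. pfkB (b1723) was the highest at 0.33, and was at least 2-fold higher with size factors. The 12 genes of pyruvate metabolism and fermentation had a median of -0.18 (percentile 35.9), from pflA (b0902) at 0.55 to the lactate dehydrogenase gene ldhA (b1380) at -3.07. The 18 tricarboxylic acid cycle genes had a median of -0.50 (percentile 31.9), with fumB (b4122) at 1.21 (0.85 to 1.57) and the malate synthase gene aceB (b4014) at -3.69.

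Of the transport, export and membrane lists, the outer membrane proteins were the 1 list that stood apart. The 29 inner membrane transporters had a median of -0.34 (percentile 88.8), with kefC at 3.97 and the potassium uptake gene trkH (b3849) at -2.83. The 21 protein export genes had a median of -0.46 (percentile 66.7), from bamC (b2477) at 0.87 to bamD (b2595) at -2.17. The 20 periplasmic proteins had a median of -0.77 (percentile 16.2), from ppiA (b3363) at 0.55 to the lysozyme inhibitor gene ivy (b0220) at -4.80 (-7.09 to -3.24, with 3 disome reads). For 10 iron uptake genes the median was -0.05 (percentile 95.7), with fhuD at 4.28 and entB (b0595) at -1.83. The 21 genes of fatty acid and phospholipid synthesis had a median of -0.46 (percentile 48.7). Their highest member was fabB (b2323) at 0.45 and their lowest pgpA.

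Of 31 cell division and murein genes, 21 were at least 2-fold lower and 1, ddlB (b0092) at 2.29, at least 2-fold higher. ddlB encodes a D-alanine ligase. With size factors the counts were 16 lower and 3 higher. Their median was -1.86 against -1.19 for matched lists (percentile 5.6), with mreD (b3249) lowest at -4.64 (-7.70 to -2.76, with 2 disome reads) and ftsZ, the division ring gene, at 0.90. Of 38 amino acid biosynthesis genes, 21 were at least 2-fold lower and 3 at least 2-fold higher, or 14 and 6 with size factors (median -1.29, percentile 37.7), from carB (b0033) at 1.74 to argG (b3172) at -3.87. The 19 nucleotide biosynthesis genes had a median of -0.66 (percentile 60.3), from purA (b4177) at 0.34 to pyrD (b0945) at -4.29 (-7.36 to -2.40, with 2 disome reads). The 26 DNA replication and repair genes had a median of -0.60 against -1.09 for matched lists (percentile 94.6), from holA at 4.13 to the initiator gene dnaA (b3702) at -2.58. RNA polymerase and transcription factor genes numbered 14 (median -0.23, percentile 75.4), from rpoZ (b3649) at 0.28 to rpoE (b2573), with 182 monosome and 18 disome reads. The remaining lists were chaperones and proteases (16 genes, median -0.39, percentile 49.9), with dnaJ (b0015) at 0.59 and clpB (b2592) at -2.35, and cold shock genes (11 genes, median -0.10, percentile 82.2). In the cold shock list rbfA (b3167) stood at 0.35 and cspG (b0990), with 121 and 3 reads, was 15.9-fold lower (5.33 to 78.4). Oxidative stress genes (15 genes) had a median of -0.50 (percentile 38.8), with msrA (b4219) at 1.96 and soxS (b4062) at -3.71 (-6.01 to -2.12, with 3 disome reads). Iron-sulfur cluster genes (9 genes) had a median of -1.73 (percentile 14.1), with sufS (b1680) at 2.28 and iscA (b2528) at -3.28. Of the flagellar and chemotaxis genes 6 were measured (median -1.96, percentile 53.1), with flgG (b1078) at -2.74 next to flgF at 4.10.

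The last comparison set the ratio against coding length, because a disome needs room for a pair of ribosomes. The 4 genes of at most 20 codons with at least 100 reads (pheM, pheL, hisL and ypfM) held 6774 monosome and 13 disome reads, and all 4 were at least 2-fold lower. Of the 13 genes of 21 to 50 codons, 7 were at least 2-fold lower and 6 lay above the median of all genes, among them tnaC and rpmH. The 119 genes of 51 to 100 codons had a median log2 ratio of -1.27, and 67 were at least 2-fold lower. Over all 1729 genes the ratio was weakly related to length (Spearman rho across genes 0.085, bootstrap interval over genes 0.037 to 0.132). The median log2 ratio was -1.02 in the fifth of shortest genes and -0.74 in the fifth of longest genes. With a minimum of 500 reads, over 1039 genes, rho was 0.0076.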

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

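In this part the pattern of related genes was picked after the gene counts were seen, and the tests were fixed before their results, but the judgement that the comparison with other relatives cannot decide was made after its result was seen.

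Pseudogenes lie outside the named genes and the list medians, and their 131 rows together held 73237 monosome reads and 14639 disome reads. Most came from nmpC (34252 and 8297 reads), a porin pseudogene, and gatC (32960 and 5893), a galactitol transporter pseudogene. The locus b4600 matched no gene of the reference table, spans 7279 codons in the files, and held 932 monosome and 12 disome reads.

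Of the relatives of ompC and gapA, 3 had many monosome reads and almost no disome reads, the porin gene ompN (2016 and 0), the porin pseudogene yedS (657 and 0) and the pseudogene gapC (1632 and 13), while nmpC, also related to ompC, at -0.71, and epd, related to gapA, with 607 and 288 reads at 0.26, did not show this, and phoE, another relative of ompC, had 0 and 0 reads. Too few reads cannot account for this, since 1020 disome reads would be found in these 3 genes at the median ratio of genes of the same mean expression, and 13 were found. A candidate explanation is that some monosome reads of ompC and gapA were counted on these relatives while disome reads were not, and 8 other relatives of abundant genes had a median at percentile 18.7 of matched lists, which met the bound of 10 set beforehand against it. That bound supposed that the 8 genes hold mostly shared reads, but 4 of them held more monosome reads per 1000 of their relative than the 3.22 of gapC, the highest of the 3 genes, so the set was then judged unable to decide and the explanation stays open. No biological explanation was tested.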

How the results depend on the processing

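The number of genes at least 2-fold higher in the disome library, 102 with library totals, was 267 with trimmed-mean factors and 329 with size factors, which move every ratio up by one amount. With a minimum of 500 reads it was 31, and with a minimum of 1 read and a prior count of 0.5 it was 306. The number at least 2-fold lower, 800, became 335 with a minimum of 500 reads and 1623 with a minimum of 1 read and that prior count together, where 1039 and 3583 genes were compared in place of 1729. The Spearman correlation across genes, 0.845, was 0.883 with a minimum of 500 reads, 0.898 with a minimum of 1 read and a prior count of 0.5, and 0.879 with 50 monosome reads, and the rho of ratio with length, 0.085, was 0.0076 with a minimum of 500 reads. For these relations the cause was not tested. Between 3 and 5 lists stood apart in each setting. Leader peptides, outer membrane proteins and nucleoid-associated proteins stood apart lower in 12 of 12 alternatives that bear on lists, and acid and general stress in 10 of 12. Cell division and murein joined them in 3 alternatives, iron-sulfur cluster assembly in 1 and the respiratory chain, on the higher side, in 1. No list that stood apart reversed. The other scalings add 1 constant to every ratio, and pseudogenes were in no list median. These alternatives could hardly move a list, so 12 of 12 overstates the check. Matching on length used 3 bins, which are wide against the median of 27 codons of the leader peptides. Of 56 named genes at least 2-fold higher or lower, nuoI, tnaB and pgi came within 2-fold under another scaling, and the interval bounds of fumB, osmC and tnaB lay within 2-fold. Of 24 named genes within 2-fold, 15 passed 2-fold higher with trimmed-mean factors and 19 with size factors, among them tnaC, secM, ompA, ompC and lpp. For a single gene this says little more, since the read minimums leave its ratio as it is and each scaling adds 1 constant. The 10 highest genes were not measured with minimums of 500 reads or 50 monosome reads. Depth limits the disome library most, where 1439 of 4294 genes had no read. The comparison of proline runs was not run, nor were alternatives for normalized units or without structural RNAs, since the files hold counts and no listed RNA name matched. No library could be left out, with 1 of each kind.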

Other observations

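In this part the genes and the O-antigen cluster were picked after their values were seen, and the test of short reading frames against slightly longer ones, with the genes left out of it, was chosen after its result was seen.

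A gene cluster outside the fixed lists had mostly low ratios. The cluster that encodes O-antigen sugar synthesis and transfer (rfbB to wbbK) held 19300 monosome and 1466 disome reads over 10 genes, a pooled log2 ratio of -2.38, and 8 of the 10 were at least 2-fold lower. wbbK stood at -6.22 (-7.10 to -5.47), rfbC at -5.60, wbbH at -4.86, rfbX at -4.55 and glf at -3.67, while rfbD stood at 1.13. After the median of genes of the same expression was taken off, the lowest of 339 windows of 5 neighbouring measured genes ran from glf to wbbK (median -3.08). In 1000 shuffles within expression bins, 3.8% held a window as low. The cluster was picked from these same values, so the shuffles cannot set a chance run aside. Across 483 neighbouring gene pairs at most 50 nt apart, Spearman rho of the adjusted ratio was 0.054, within the -0.098 to 0.091 that shuffles gave.

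The potassium efflux genes kefB and kefC both had high ratios, 3.82 (3.13 to 4.59) and 3.97 (3.28 to 4.73), each with 20 monosome reads. With so few monosome reads, either gene could pass the read minimum over both libraries only with a high ratio. That both ratios were high therefore follows from this rule and is not evidence of a trait shared by these genes. raiA, a ribosome hibernation factor gene and among the 10 most counted genes of the monosome library with 297594 reads, stood at -0.99 (-1.01 to -0.98), where genes of the same expression had a median of 0.09. hpf, a related hibernation factor gene, stood at -1.57. fimA, the main fimbrial subunit gene, had 4002 monosome and 5143 disome reads and a log2 ratio of 1.70 (1.64 to 1.76). Next to ygfX at 4.65, sdhE stood at -2.99 and ygfZ at 0.07.

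Reading frames of at most 20 codons held 13 disome reads against 6774 monosome reads, where 1674 disome reads would be found at the median ratio of genes of the same expression, so depth does not account for it. Their pooled log2 ratio minus that of genes of 21 to 50 codons was -7.77 (bootstrap interval over genes -11.8 to -6.87). The short group has 4 genes, and ypfM held 4820 of its monosome reads and all 13 disome reads. Its pooled ratio and this interval therefore rest largely on that gene. The longer group's pooled ratio of 0.08 rests on tnaC, rpmH and rpmJ, and its median was -2.68, so the difference was -7.65 without tnaC, -5.78 without all 3, and -4.25 between medians with genes without disome reads at their bound. This is consistent with a frame too short for a pair of ribosomes. It does not cover the 7 of 13 genes of 21 to 50 codons that were also at least 2-fold lower, among them yobF (48 codons, 3 disome reads), ilvL (33 codons) at -5.13, mgtS (32 codons) at -4.88, acrZ (50 codons) at -3.98 and ecnB (49 codons) at -3.64. The rule that assigned disome footprints to genes is not given and stays open.

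The ratio was higher in genes of higher expression, from a median log2 ratio of -2.11 in the lowest of 5 equal bins of mean expression to -0.22 in the highest. The highest bin, thinned to the reads of the lowest, stayed 1.89 above it (bootstrap interval 1.721 to 2.104). The median of the highest bin was -0.22 before and after thinning, so fewer reads by themselves did not lower its ratios. Thinning cannot decide whether low counts account for the lowest bin. Genes there also had to pass the read minimum, and thinning the highest bin does not reproduce that selection. The minimum was set on reads summed over both libraries, and the monosome library was the deeper one. At the lowest mean expression it therefore admits only genes with low ratios. The low median of the lowest bin is thus partly set by this rule, and how much of the span it accounts for was not tested. Within 5 bins of coding length, rho of ratio with mean expression was between 0.427 and 0.539, so this relation remained among genes of like length. Mean expression holds the disome count, which can raise rho by itself. Length is therefore not set aside for a relation with monosome level alone. With 951 genes chosen and ranked by at least 500 monosome reads alone, rho was 0.337 (0.271 to 0.399), against selection by the minimum among these genes. Over 5 bins of these genes by monosome reads the median log2 ratio went from -1.05 in the lowest to -0.13 in the highest, a smaller span. With monosome reads per codon, over all 1729 genes, rho was 0.192 (0.146 to 0.239), against 0.451 with mean expression, which itself holds the disome count. No biological explanation was tested, and RNA fragments in the monosome library that did not come from ribosomes, also not tested, stay open.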
